A study of Homo sapiens with 4 samples.

How the data were processed

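The series measured enhancer activity by STARR-seq in MDA-MB-231, a human breast cancer cell line of mesenchymal, triple-negative type. In STARR-seq, genomic fragments are placed downstream of a minimal promoter on a plasmid, so that an active fragment is copied into its own reporter transcript, and the reporter RNA is sequenced. The plasmid library held sheared DNA of the same cell line. Cells received DMSO, SHP1705 at 10 µM, MG132 at 100 nM, or both drugs, and RNA was taken at 8 h, per the labels. There was 1 library and 1 peak list per treatment, so no spread between replicates could be computed and no p-value is given.

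Per the submitters' processing notes, Trimmomatic, FastQC, Bowtie2 and MACS2 were used with the hg38 build. Versions of the first 3 tools are not given in the sources used here. Per the file headers, peaks were called for each library alone with MACS 2.2.6 at a q limit of 0.01, with duplicate fragments kept, no control library and a local background taken over 10000 bp. The fragments counted were 29717604 for DMSO, 118324303 for SHP1705, 27289266 for MG132 and 28331486 for the combination. The signal of a peak is the pileup at its summit, the number of fragments that cover it, as deposited by the authors without scaling for depth. The −log10 p and −log10 q of a peak are those the authors' peak caller gave. The fold of a peak is the ratio of its pileup to the local background, also as deposited. The fold, −log10 p and −log10 q are the authors' and serve here to describe, rank or filter peaks within their own list. Regions held by several lists are an exception, as they are ranked by the lowest fold among those lists. Pileups are also set side by side between lists, as raw heights or per 1000000 fragments, with no further normalization. With a background averaged over 10000 bp, the fold of an isolated pile of fragments cannot exceed about 10000 divided by the fragment size, or 28.9 in DMSO, 33.4 in SHP1705, 28.2 in MG132 and 28.2 in the combination. The highest folds therefore mark isolated piles and not the tallest peaks. The caller's minimum peak width was the fragment size, which was 346 bp in DMSO, 299 bp in SHP1705, 354 bp in MG132 and 355 bp in the combination. Narrow peaks that SHP1705 could hold could not be called in the other lists.

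From these files, peaks on chromosomes 1 to 22 and X were merged across the 4 lists wherever they shared at least 1 bp. A region was gained in a treatment when it held a peak in that list and none in the reference list, and lost in the reverse case. Both words describe peak calls in single libraries. Overlap between lists was set beside 100 random placements of the same peaks on their chromosomes. Placement could fall in assembly gaps, which lowers the random value. The counts of the 15 possible presence patterns were set beside a Rasch model, in which lists differ only in length and regions only in strength, with the central 95% of 1000 simulated counts. The model matches the count in all 4 lists by construction. It also matches the total over the patterns held by any given number of lists. Excesses and shortfalls among patterns held by the same number of lists therefore offset. On 10 simulated sets with 500 regions planted in the pattern of both SHP1705 lists, the mean excess over the model was 340, and with none planted it was -40, over 159947 regions in the last set. In that pattern an excess over the model is therefore a low estimate, and small shortfalls arise with nothing planted. The other patterns were not checked in this way. A first version of this check asked for the whole planted number and did not pass, after which its limits were widened. Shares carry Wilson 95% intervals, which cover counting error only, since duplicates are not independent molecules.

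Genes came from the RefSeq table of GRCh38.p14, whose primary chromosomes have the coordinates of hg38. It holds gene starts and ends and no strand or exons, so the planned distance to a transcription start was replaced by the distance to either end of a protein-coding gene, and the planned exon and intron shares were not computed. No genome sequence was used, so the 21 planned motifs, the GC-matched windows and the filter on repeats were not analysed here. For gene lists, the number of members with a region within 10 kb of either gene end was set among 10000 random lists matched on the number of regions nearby, in 5 bins, over 19970 protein-coding genes. The 14 lists were the clock core loop, clock protein turnover, proteasome subunits, heat shock and chaperones, NRF2 oxidative stress, ATF4 and unfolded protein response, NF-kB and inflammatory, p53 targets, interferon response, AP-1 and immediate early genes, mesenchymal and basal breast, luminal breast, blood and liver, and cell cycle. Of their 326 names, 323 memberships were matched. In simulated lists with no effect, 7.5% fell past the outer percentiles of 2.5 and 97.5 where 5% was intended, so these percentiles are somewhat too extreme. The simulated genes were flagged independently of their neighbours and at rates unlike those of some real sets. The 7.5% therefore need not hold for the real lists. The random lists also draw genes singly, while members that lie close together can be counted for the same region. This can make the percentiles more extreme still. A list with 18 of 25 members near a region was found in 100% of simulations. Ribosomal protein and histone genes were added as 2 further lists after the data were examined.

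Named genes followed a rule set before the data were examined. For each drug against DMSO it takes the 8 gained and 8 lost regions of highest fold within 10 kb of a protein-coding gene end, named by the nearest end. It also takes the 5 regions of highest fold in each pattern described, ranked by the lowest fold among the lists that hold them. From each gene list it takes up to 4 members of highest fold, and PER1, PER2, CRY1, CRY2, NR1D1 and DBP are given in every list. Some regions that this rule selects are not reported here. Over regions with a SHP1705 pileup of at least 10000 and a peak in another list under 10% of that height, with summits within 250 bp, pileups were set against a constant share with the central 95% of 1000 Poisson draws. The most abundant transcripts, the tallest peaks and the mitochondrial peaks were singled out after their values were seen. Alternatives were a −log10 q of at least 5, a fold of at least 3, equal list length at 47822 peaks, 50% reciprocal overlap, summits within 250 bp, all sequences, 5 kb in place of 1 kb and 50 kb in place of 10 kb. Alternatives added after seeing the data were leaving the SHP1705 list out, regions outside every annotated gene, peaks at least 1.5 fragment sizes wide, and a common minimum width of 355 bp. Computation used python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.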

Results

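Enhancer activity of genomic fragments was measured by STARR-seq in MDA-MB-231 cells kept for 8 h in DMSO, in 10 µM SHP1705, described by the submitters as a stabilizer of the clock repressor CRY2, in 100 nM MG132, a proteasome inhibitor, or in both. There was 1 library per treatment. The SHP1705 library held 118324303 fragments and the others 29717604 (DMSO), 27289266 (MG132) and 28331486 (combination). Differences between lists therefore compare libraries, with no replicate check. A peak near a gene reports the activity of a plasmid fragment, or RNA that aligns there, and not that gene's expression.

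The location of the SHP1705 peaks set that list apart from the other 3. On chromosomes 1 to 22 and X there were 85840 peaks in SHP1705, 69842 in MG132, 57174 in the combination and 47822 in DMSO. Per 1000000 fragments the order differed, with 725 in SHP1705, 2559 in MG132, 2018 in the combination and 1609 in DMSO. In SHP1705, 56.5% of summits (95% interval 56.2 to 56.8) lay inside a protein-coding gene, against 37.2% in DMSO, 39.3% in MG132 and 38.1% in the combination. Within 1 kb of an end of a protein-coding gene lay 12.9% of SHP1705 summits (12.7 to 13.1), against 3.96% in DMSO (3.79 to 4.14), 3.57% in MG132 (3.43 to 3.71) and 3.56% in the combination (3.41 to 3.71). Among the 47822 strongest peaks of each list this share was 19.3% in SHP1705, 2.58% in MG132 and 2.78% in the combination. SHP1705 peaks lay outside every annotated gene in 31.8% of cases, against 50.6% in DMSO, 47.8% in MG132 and 49.6% in the combination. The median peak width was 431 bp in DMSO, 449 bp in SHP1705, 432.5 bp in MG132 and 434 bp in the combination.

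**Figure D1:**
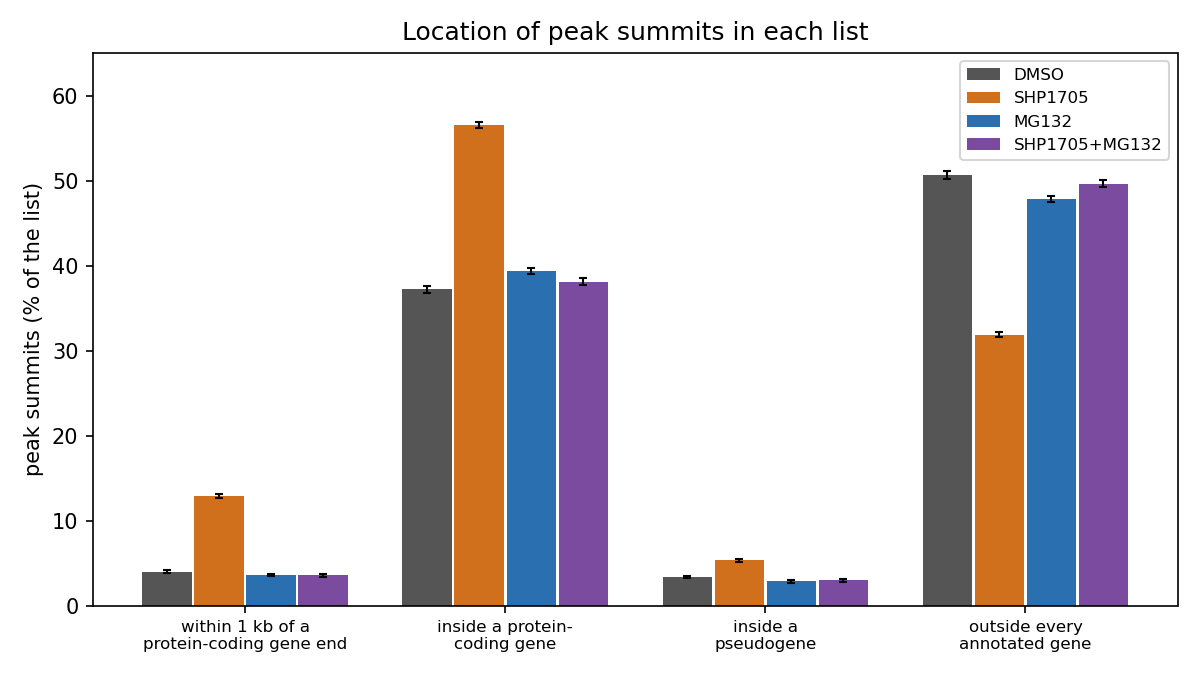
Share of each list's peak summits (%, bars, with Wilson 95% intervals for counting error) in 4 kinds of location, for the 4 treatments; the kinds overlap. SHP1705 stands at 12.9% near gene ends and 56.5% inside protein-coding genes, and the other lists between 3.56% and 3.96% and between 37.2% and 39.3%.

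The tallest SHP1705 peaks lay on abundant transcripts and on their processed pseudogenes, which are intronless genomic copies of mRNAs. The tallest of all covered EEF1A1P5, a copy of the translation elongation factor EEF1A1, at chromosome 9, 133019443 to 133021062 (hg38), with a pileup of 402266 fragments. It was followed by TMSB4XP8 with 304030, FTH1P7 with 290730, RPL13AP5 with 262269 and FTLP3 with 247291. Of the 100 tallest peaks, 70 overlapped a pseudogene in SHP1705, 0 in DMSO, 1 in MG132 and 1 in the combination. In DMSO, MG132 and the combination, 97, 98 and 99 of the 100 tallest peaks overlapped no annotated gene, and the tallest lay on chromosome 1, at 125179321 to 125180632 in DMSO with 226046 fragments. No filter on repeats was run, so fragments piled up on repeated sequence cannot be told apart from reporter activity at these peaks. At ACTB, which encodes cytoskeletal actin, the highest pileup was 186461 in SHP1705, 1803 in DMSO, 1816 in MG132 and 1523 in the combination, or 1576, 60.7, 66.5 and 53.8 per 1000000 fragments. VIM, the mesenchymal intermediate filament vimentin, reached 589 per 1000000 fragments in SHP1705 and 7.44 in DMSO, and the noncoding RNA MALAT1 reached 983 and 42.5. The tallest SHP1705 peaks in the ferritin genes FTL and FTH1 were 301 bp and 317 bp wide, under the minimum that could be called in the other lists, which had no peak inside these genes.

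Few peaks were shared between treatments. Of 223513 merged regions, 200099 (89.5%) held a peak in 1 list only, 15111 in 2 lists, 3719 in 3 and 4584 (2.05%) in all 4. DMSO peaks overlapped MG132 peaks in 18.5% of cases (18.2 to 18.9), where random placement gave 2.30%. They overlapped SHP1705 peaks in 18.1% (17.7 to 18.4), against 3.45% at random, and combination peaks in 17.0% (16.7 to 17.3), against 1.89%. Of the combination's peaks, 16.3% overlapped MG132 peaks and 15.5% overlapped SHP1705 peaks, against 2.31% and 3.43% at random. MG132 peaks overlapped SHP1705 peaks in 14.4% of cases, against 3.42%. Regions shared by DMSO and MG132 lay outside every annotated gene in 67.2% of cases (66.3 to 68.2), against 46.8% of DMSO regions without an MG132 peak. Without a filter on repeats, part of this sharing could come from fragments piled up on repeated sequence, which was not tested. The order of these shares depends on list length: among the 47822 strongest peaks of each list, DMSO overlapped SHP1705 in 13.9% of cases, MG132 in 9.85% and the combination in 11.3%, and the combination overlapped MG132 in 9.43%.

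The 5 regions of highest fold in all 4 lists were named for FABP12, C1orf185, NHSL2, RNF169 and GOLGA3, and 4 of them lay on pseudogenes of abundant mRNAs. The FABP12 region (chromosome 8, 81521674 to 81522103 in DMSO) covered the ferritin copy FTH1P11. The C1orf185 region covered CFL1P2, the RNF169 region RPS12P22, and the GOLGA3 region RPS11P5, a ribosomal protein copy. The NHSL2 region on chromosome X covered LOC121627959. Regions in all 4 lists lay near 12 of 24 mesenchymal and basal breast genes (percentile 100 among random lists), with the highest folds at TGFBI, VIM, FN1 and PLAU. At VIM the highest pileup was 69679 in SHP1705, 221 in DMSO, 263 in MG132 and 197 in the combination. At TGFBI it was 42820, 273, 292 and 218. A peak in all 4 lists therefore does not mean equal height, and the source of the low peaks was not settled. Regions of this kind lay near 9 of 25 heat shock genes (percentile 99.99), among them HSPB1, HSPD1, HSPB8 and HSPA9. They lay near 8 of 22 luminal breast genes (99.98), among them the keratins KRT8, KRT18 and KRT19. KRT8 and KRT18 overlap on the genome, so the same region can count for both. The AP-1 list had 7 of 23 members (99.9), including FOSL1, CCN1 and JUN, and the ATF4 list 6 of 20 (99.8), including CALR and ATF4. In all, 5 of 14 lists lay past the outer percentiles, where 1.05 would at the rate of the simulated lists. That rate need not hold for these counts, which were not run under other settings. The clock core loop had 1 of 21 (29.6), BHLHE40, and the interferon and the blood and liver lists had 0 of 24 and 0 of 22.

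SHP1705 was compared with DMSO to ask which fragments become active or inactive when CRY2 is stabilized. SHP1705 had 76983 regions without a DMSO peak, DMSO had 39024 without a SHP1705 peak, and 8597 were shared. Gained regions lay inside a protein-coding gene in 59.1% of cases (58.7 to 59.4) and lost regions in 38.2% (37.7 to 38.6). The 8 gained regions of highest fold were named for POTEF, FAM216A, QSOX1, OOEP, NATD1, CAGE1, POTEH and ZNF616. Copies of mRNAs not annotated as pseudogenes were not counted, and 4 of the 8 covered an annotated pseudogene of an abundant mRNA. These were RPL31P49 near FAM216A, RPL39P3 in OOEP, EIF1P5 near NATD1 and RPL37P23 near ZNF616, where the fold was 32.9 at chromosome 19, 52143020 to 52143324. The QSOX1 region, at the end of a gene for a secreted sulfhydryl oxidase, lay at chromosome 1, 180154862 to 180155194. The lost regions of highest fold were near RAD21L1 (chromosome 20, 1258032 to 1258412), MYT1L, C2orf42, LOC124904103, ARHGAP35, MACROD1, GPIHBP1 and TERB2, with folds from 28.2 to 28.5 in DMSO.

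Within each of the 6 clock genes examined, SHP1705 had more peaks than any other list, while within 10 kb of CRY2 it had 3 and MG132 had 4. SHP1705 also had the most summits inside protein-coding genes as a whole. It had 48514, against 17786 in DMSO, 27477 in MG132 and 21769 in the combination. The counts below therefore do not set the clock genes apart. PER1 (chromosome 17, 8140472 to 8152404), a clock repressor, held 4 peaks in SHP1705, 1 in MG132, 0 in DMSO and 0 in the combination. PER2 held 3, 0, 1 and 0 in the same order. CRY1 held 5 in SHP1705, 3 in MG132, 0 in DMSO and 2 in the combination. CRY2, the repressor that SHP1705 is meant to stabilize, held 3, 2, 0 and 0. NR1D1, which encodes the nuclear receptor REV-ERB alpha, held 2, 0, 0 and 1, and the clock output factor DBP held 2, 1, 0 and 0. The tallest NR1D1 peak in SHP1705, at chromosome 17, 40092919 to 40093679, lay at a gene end with 1255 fragments.

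Gained SHP1705 regions lay near 16509 of all 19970 protein-coding genes (82.7%), which leaves little room for a list to stand above chance. They lay near 20 of 21 clock core loop genes (percentile 83.7), led by CIART, CRY1, NR1D2 and DBP, and near 16 of 16 clock protein turnover genes (96.7). Counts were 33 of 36 proteasome subunits (64.0), 20 of 20 NRF2 genes (93.8), 18 of 20 ATF4 genes (74.7), 19 of 22 NF-kB genes (52.9), 20 of 20 p53 targets (96.1), 23 of 24 interferon genes (90.3), 20 of 23 AP-1 genes (72.8), 21 of 24 mesenchymal genes (55.8), 15 of 22 blood and liver genes (55.1) and 28 of 28 cell cycle genes (97.1). Heat shock genes, with 20 of 25 (1.31), and luminal genes, with 16 of 22 (0.485), lay below the random lists. DMSO had regions near 20 of 25 heat shock genes (99.7) and 21 of 22 luminal genes (100), and SHP1705 near 25 of 25 (86.3) and 21 of 22 (68.8), so the low count is of regions that DMSO lacks, not of SHP1705 regions. At equal list length gained regions lay near 19 of 25 heat shock genes (16.3), no longer past the outer percentiles, and near 15 of 22 luminal (1.54), 19 of 22 NF-kB (99.4), 28 of 28 cell cycle (99.3), 20 of 20 p53 (97.8) and 15 of 16 clock protein turnover genes (97.7). Ribosomal protein genes had 74 of 77 (99.985) and replication-dependent histone genes 52 of 69 (26.9), both lists chosen after seeing the data. Lost regions lay near 2 of 22 NF-kB genes (0.28), NFKB2 and BIRC3, and 5 of 28 cell cycle genes (0.465), including CCNB2 and MKI67. DMSO itself had regions near few of these, with 7 of 22 NF-kB genes (9.76) and 10 of 28 cell cycle genes (3.16), and its peaks are the lost regions of every drug. With lists of equal length 41117 regions were gained and 41069 lost.

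MG132 was compared with DMSO to ask which fragments respond to proteasome inhibition. Among gained regions the interferon genes lay past the outer percentiles, with 20 of 24 members near one (percentile 99.3), led by IFI44, IFIH1, ISG20 and the antiviral GTPase MX1. At equal list length the count was 18 of 24 (percentile 99.6). Within 50 kb, where 93.2% of all genes lay near a gained region, it was 22 of 24, the same as the random median, so that distance cannot set a list above chance. The combination, which also contains MG132, did not repeat the interferon count, with 10 of 24 at equal list length (percentile 25.4). Against MG132, it had only gained regions near 1 interferon gene and only lost regions near 9. Over all lists, drugs and directions, 11 of 84 counts lay past the outer percentiles. At the rate of the simulated lists, which need not hold for the real ones, 6.3 would. MG132 had 60754 gained, 38748 lost and 8873 shared regions against DMSO, or 43049 gained and 42934 lost at equal list length. Among the gained regions of highest fold were those near OTOP1 (chromosome 4, 4223284 to 4223771, fold 27.9), LOC124904439, TBC1D2, BOP1, PUM3, FBXO36 and DPP4, which encodes a cell surface peptidase. The BOP1 region (chromosome 8, 144281377 to 144281855) was also within 10 kb of HSF1, the heat shock transcription factor. The lost regions were near RAD21L1, MYT1L, C2orf42, LOC124904103, ARHGAP35, ZNF750, GPIHBP1 and LOC124902565. Gained regions lay inside a protein-coding gene in 41.5% of cases (41.1 to 41.9) and lost ones in 40.0% (39.6 to 40.5).

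Gained MG132 regions did not set the stress lists apart in the full lists, while at equal list length ATF4 genes lay below the random lists (5 of 20, percentile 1.03). In the full lists gained regions lay near 23 of 36 proteasome subunits (percentile 56.2), with ADRM1, PSMB1 and PSMB2 leading, and near 18 of 25 heat shock genes (78.5), including AHSA1 and HSPH1. Counts were 11 of 20 NRF2 genes (26.7), with SRXN1 and HMOX1, 10 of 20 ATF4 genes (28.0), with DNAJB9 and ATF3, and 11 of 21 clock core loop genes (18.4), with CRY2 and NFIL3. They were 10 of 16 clock protein turnover genes (59.3), 10 of 22 NF-kB genes (18.4), 10 of 20 p53 targets (10.1), 14 of 23 AP-1 genes (81.3), 14 of 24 mesenchymal genes (38.4), 10 of 22 luminal genes (6.95), 7 of 22 blood and liver genes (22.7) and 13 of 28 cell cycle genes (3.90). Lost regions lay near 3 of 22 NF-kB genes (0.52) and 6 of 28 cell cycle genes (0.36). At equal list length NF-kB genes, with 7 of 22 (18.2), were no longer past the outer percentiles, cell cycle genes had 9 of 28 (1.03), and luminal (19 of 22, 99.9), mesenchymal (17 of 24, 98.8) and AP-1 genes (16 of 23, 98.0) lay above the random lists. Lost regions are DMSO peaks, so these counts also depend on how many DMSO peaks lie near a list, and are not by themselves a response to MG132. In the full lists, lost and gained regions occurred together near 13 proteasome subunits and 10 heat shock genes.

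The combination was compared with DMSO for the joint action of both drugs. Its gained regions of highest fold lay near PLA2G4A (chromosome 1, 186989495 to 186989976), a cytosolic phospholipase, OR5H1, C6orf62, TEAD4, CLTRN, FUCA1, DDX10 and IFT25, with folds from 27.3 to 27.7. There were 48828 gained, 39463 lost and 8158 shared regions, or 42337 gained and 42218 lost at equal list length. The lost regions were near RAD21L1, MYT1L, C2orf42, LOC124904103, ARHGAP35, ZNF750, MACROD1 and GPIHBP1. Regions lost near luminal breast genes numbered 16 of 22 (percentile 99.6), among them PGR, FOXA1, CLDN3 and SPDEF, and those near mesenchymal genes 16 of 24 (98.5), among them CAV2, SPARC, MMP1 and PLAU. DMSO had regions near 21 of 22 luminal (100) and 19 of 24 mesenchymal genes (99.8), so these lists also held more DMSO peaks than random lists. Cell cycle genes had 6 of 28 (0.275) and NF-kB genes 4 of 22 (2.07), the latter 7 of 22 (19.3) at equal list length. Gained regions lay near 23 of 36 proteasome subunits (91.6), led by PSMD1 and PSMA3, 16 of 25 heat shock genes (85.4), 12 of 20 NRF2 genes (76.7), led by SLC7A11, 10 of 20 ATF4 genes (60.5), 11 of 21 clock core loop genes (52.2), led by CIART and CRY1, and 10 of 24 interferon genes (16.7). Gained regions of all 14 lists lay between the 16.7 and 91.6 percentiles in this comparison.

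The 3 comparisons share the same DMSO list, so their lost regions are largely the same peaks. Over the 84 combinations of list, drug and direction, 11 lay past the outer percentiles, where 4.2 would at 5% and 6.3 at the 7.5% found with simulated lists. Neither rate need hold for the real lists, so the excess over them is not a test. Among lists of equal length 16 lay past the outer percentiles, including 8 of the 11. With 50 kb in place of 10 kb, where 80.2% to 97.2% of all genes lay near such a region, 2 did, and neither was among the 11: gained MG132 regions near NF-kB genes (17 of 22, percentile 2.12) and lost combination regions near interferon genes (15 of 24, percentile 0.96). Regions gained both in SHP1705 and in MG132 numbered 4433, where the Rasch model gave 5071 and independence over all regions gave 20925. Regions gained both in MG132 and in the combination numbered 3637, against 3634 by the model. With a single DMSO library, gains in 2 treatments share 1 control.

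Against SHP1705 alone, the combination had 48153 gained, 76747 lost and 8833 shared regions. Lost regions lay inside a protein-coding gene in 59.1% of cases (58.8 to 59.5) and gained ones in 39.1% (38.6 to 39.5). Against MG132 alone there were 47653 gained, 60294 lost and 9333 shared regions, with 40.6% of gained (40.2 to 41.1) and 41.5% of lost regions (41.1 to 41.9) inside a protein-coding gene. At equal list length 43080 regions were gained and 43009 lost against SHP1705.

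Regions held by both lists of a drug only lay below the model for SHP1705 and above it for MG132 in the full lists. The model fixes the total over all pairs of lists, so these departures offset by construction. Each pair with SHP1705 lay below it and each pair without SHP1705 above it. The ratio for both MG132 lists, 1.12, was below those of DMSO with MG132, 1.15, and with the combination, 1.17. The excess is therefore not particular to MG132. Regions in both SHP1705 lists only numbered 2603, against 3020 expected (2920 to 3136). They were led by NRDC (chromosome 1, 51878255 to 51878737 in SHP1705), DTD1, CPLX1, TIMM21 and ABI2. Some of these pairs of peaks overlapped only at their edges. At TIMM21 the peak lay at 74148544 to 74149115 in SHP1705 and at 74149080 to 74149488 in the combination. Regions in both MG132 lists only numbered 2664, against 2377 (2286 to 2469), and those of highest fold included regions near OR14K1, DUSP10, OR2T12 and PEG3. Here too some pairs met only at their edges. At OR2T12 the MG132 peak ended at 248306623 and the combination peak began at 248306604. At equal list length both lay below the model, with 1376 against 1784 for SHP1705 and 1455 against 1787 for MG132. Outside every annotated gene the MG132 count lay within the simulated range, with 1534 against 1508 (1438 to 1588). Among peaks at least 1.5 fragment sizes wide it was 389 against 111. In the full lists, the pattern of DMSO and combination only held 1789 regions against 1526, and that of DMSO and MG132 only 2216 against 1927. The patterns of SHP1705 and MG132 only, with 3460 against 3813, and of DMSO and SHP1705 only, with 2379 against 2448 (2354 to 2544), did not exceed the model. The largest ratio to the model in the full lists, 1.75, was in the pattern of DMSO, MG132 and the combination without SHP1705, with 1112 regions against 635. This excess was gone at equal list length, with 535 against 526 (482 to 572), while in the 5 other settings run the ratio lay between 1.42 and 6.09. With lists of equal length DMSO and MG132 only lay below the model, with 1472 against 1782, and the largest ratio, 1.74, was that of DMSO and SHP1705 only, with 3089 against 1779. Regions in the combination only numbered 42588, against 42779 (42412 to 43123), and were led by PLA2G4A, C6orf62, TEAD4, CLTRN and FUCA1. In both SHP1705 lists only, 4 of 22 NF-kB genes (percentile 97.8), including NFKBIA and IL6, and 4 of 23 AP-1 genes (97.9), including JUNB and DUSP1, had a region. In both MG132 lists only, 4 of 22 luminal genes did (99.9), SPDEF, ERBB3, ERBB2 and TFF1. These 3 were the ones past the outer percentiles among 42 combinations of list with the patterns of both SHP1705 lists, both MG132 lists and the combination only. At the rate of the simulated lists, which need not hold here, 3.15 would be. The 3 were not run under other settings.

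**Figure D2:**
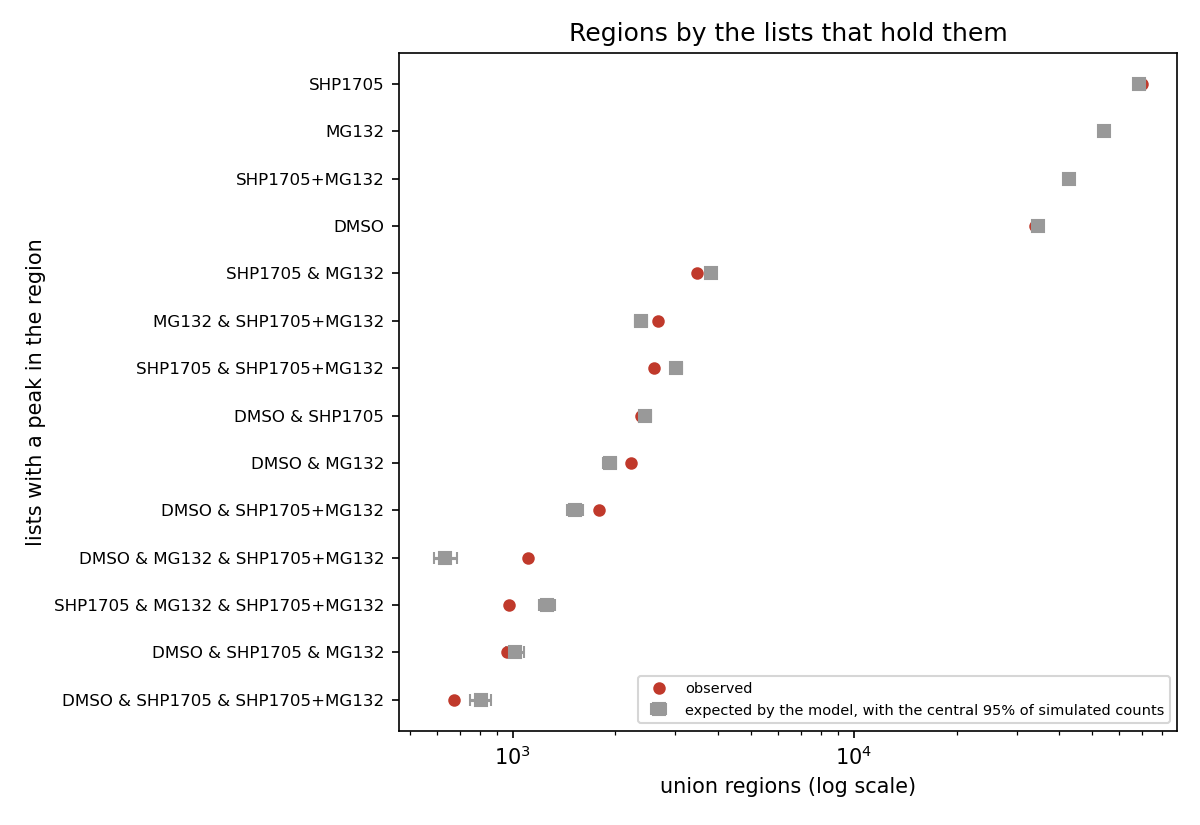
Number of merged regions (log scale) for each of the presence patterns in 1 to 3 lists, observed (circles) and expected by the Rasch model (squares, with the central 95% of simulated counts). In these full lists the pattern of DMSO, MG132 and the combination lies above the model, with 1112 regions against 635 (535 against 526 at equal list length), and that of both SHP1705 lists only below it, with 2603 against 3020.

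Sharing between lists depended on the strength of a peak differently in SHP1705 and in the other lists. With each list divided by −log10 q into 10 groups of equal size, 50.7% of the weakest group in DMSO (49.3 to 52.1) and 30.9% of the strongest (29.6 to 32.2) lay in a region shared with another list. The DMSO share was lowest, at 17.8% (16.7 to 18.9), in group 8, so it did not fall steadily with strength. In SHP1705 the shares were 9.90% (9.29 to 10.6) and 40.6% (39.6 to 41.7). MG132 had 41.5% and 31.4%, and the combination 45.9% and 28.9%.

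**Figure D3:**
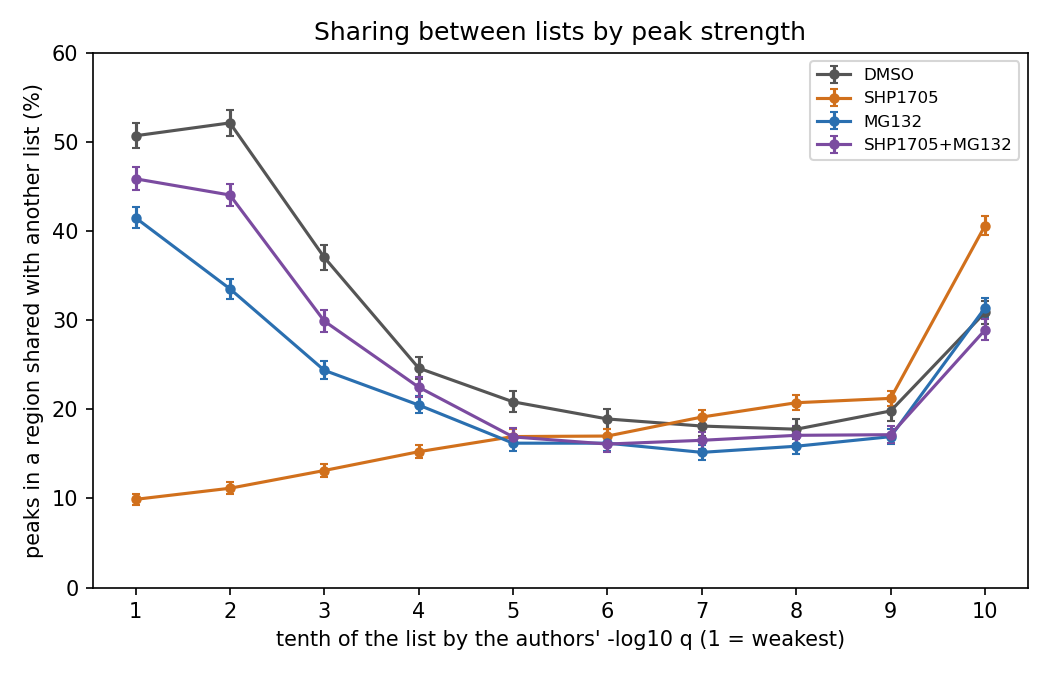
Share of peaks in a region shared with another list (%, with Wilson 95% intervals) in 10 groups of each list by the authors' −log10 q, from weakest to strongest. DMSO goes from 50.7% through 17.8% to 30.9%, and SHP1705 from 9.90% to 40.6%.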

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

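The tests of depth, of a SHP1705 effect and of duplicates, those within the SHP1705 list, of a constant share, and the gene length match were chosen after the result was seen. The prediction for ribosomal protein and histone genes was written before its result, but both gene lists were chosen after the data were seen. SHP1705 went with different values with and without MG132, and these differences were not tested between the backgrounds, since each value rests on 1 library. Peaks were 38018 more in SHP1705 than in DMSO, and the combination minus MG132 gave -12668. The share of summits within 1 kb of a gene end differed by 8.94 percentage points without MG132 and by -0.0119 with it (interval -0.216 to 0.194, which includes no difference). The share inside protein-coding genes differed by 19.3 and -1.27 points. On mitochondrial DNA, which the comparisons leave out, the tallest SHP1705 peak held 5453 fragments per 1000000, against 220 in DMSO, 228 in MG132 and 196 in the combination.

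The SHP1705 list holds more peaks in and at the ends of protein-coding genes than the others. At equal list length its gene-end share still exceeded the highest other list by 15.3 percentage points. That setting keeps the peaks of highest −log10 q and does not equalize the number of fragments, so it cannot exclude depth. ACTB stood 26.0 times as high as in DMSO for the same number of fragments, which depth alone would not give at that gene. A SHP1705 effect that does not depend on MG132 is argued against by the difference of -0.0119 points between the combination and MG132, while an effect that MG132 cancels stays open and untested. Endogenous polyadenylated mRNA in that library may account for it: ribosomal protein genes had a SHP1705 peak more often than histone genes, whose mRNAs lack poly(A) tails, by 53.8 points (38.8 to 65.4), against 23.2 in DMSO. Ribosomal protein genes are longer, with a median of 5011 bp against 494 bp. Length-matched genes gave 56.3% and 26.8%, so length makes up part of the gap. The 85.7% of ribosomal protein genes lay above all matched draws, and the 31.9% of histone genes did not stand apart (percentile 84.5). In DMSO, MG132 and the combination histone genes lay at percentiles 0.61, 7.11 and 0.44. From DMSO to SHP1705, histone genes with a peak rose from 1 to 22 of 69. Ribosomal protein genes with a peak rose from 19 to 66 of 77. Histone genes thus rose too, so the contrast alone cannot show that polyadenylated mRNA is the source.

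Most regions had a peak in 1 list only. In DMSO the strongest 10% of peaks minus the weakest 10% gave -19.8 points in the share found in another list, which argues against weak peaks missed elsewhere, and MG132 and the combination went the same way. Duplicates of single reporter fragments may account for those lists: the summit lay within 2 bp of the middle in 63.5% of DMSO peaks found in 1 list and in 1.92% of those in all 4. In SHP1705 the strongest 10% was shared more often than the weakest 10%, by 30.7 points, so missed weak peaks remain a possible explanation there. Centred summits made up 30.6% of its 1-list peaks against 1.59% of those in all 4 lists, which goes with duplicates for part of them, but less than the majority that the test asked for.

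Of the 564 SHP1705 regions with a pileup of at least 10000, 510 had a peak in DMSO, 506 in MG132 and 504 in the combination. Among those under 10% of the SHP1705 height (497, 493 and 491), the median was 0.763%, 0.743% and 0.635% of that height. Assignment of sequenced SHP1705 fragments to the other libraries, as the only source, would give a constant share, but 61.0% of 451 regions with matching summits lay outside the Poisson range of one in DMSO. Duplicates were kept and can widen the spread past Poisson even at a constant share, so this count alone cannot decide. Over regions shared by both, DMSO and MG132 heights differed from each other with an SD of 0.38 on the log2 scale. Each differed more from SHP1705 (0.56 and 0.54), where copies of SHP1705 with their own noise would differ more from each other. However, SHP1705 is the reference of both ratios, and its fragment size differed. A deviation of its own pileups would enter both SDs and cancel between DMSO and MG132, so this comparison cannot decide either. Transfer as a part or as the only source thus stays open. The test set beforehand was met, since 96% of the 50 tallest SHP1705 peaks far from genes had a DMSO peak. It was judged void once 44 of the 50 proved taller in DMSO. Endogenous mRNA in the other libraries is a further possible source and was not tested. Among length-matched genes, ribosomal protein genes with a peak lay at percentile 96.4 in DMSO, 64.0 in MG132 and 95.4 in the combination.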

How the results depend on the processing

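No paired analysis was possible because there was 1 library per treatment. The settings for wide peaks, regions outside genes, a common minimum width and leaving SHP1705 out were chosen after seeing the data. The settings on repeats and motifs were not run. Counts stayed within 1.5 times the main value with summits within 250 bp, a fold of at least 3, a −log10 q of at least 5, all sequences, a common minimum width of 355 bp, and without the SHP1705 list. At equal list length, regions gained in SHP1705 against DMSO numbered 41117, those lost in the combination against SHP1705 43009, those in both SHP1705 lists only 1376 and those in both MG132 lists only 1455, as the shorter lists hold fewer peaks. With 50% reciprocal overlap, regions in both SHP1705 lists only numbered 1663. With peaks at least 1.5 fragment sizes wide, which left 14.3% of DMSO and 50.1% of SHP1705 peaks, gained and lost regions numbered 39770 and 3637 for SHP1705, 6213 and 3818 for MG132, and 4787 and 4037 for the combination, each against DMSO. They numbered 4534 and 39917 for the combination against SHP1705, and 4644 and 6289 against MG132. Regions in both SHP1705 lists only, both MG132 lists only and the combination only were then 505, 389 and 3479. Outside every annotated gene, the same counts were 21686 and 18853, 27010 and 17955, 22387 and 18308, 22804 and 21558, 21779 and 26755, and 1030, 1534 and 19184. In this setting the combination gained more regions than it lost against SHP1705, the opposite order to the main count, and the cause was not tested. Overlap of DMSO with SHP1705 was 12.0% with reciprocal overlap, 13.9% at equal length and 17.6% at the stricter q. Reciprocal overlap and equal length gave 14.2% and 9.85% for DMSO with MG132, 12.9% and 11.3% for DMSO with the combination, and 12.3% and 9.43% for the combination with MG132. MG132 with SHP1705 gave 9.25%, 9.28% and, at the stricter q, 13.9%, and the combination with SHP1705 10.0%, 9.78% and 15.1%. Within 5 kb of a gene end lay 12.2% of DMSO, 26.6% of SHP1705, 12.0% of MG132 and 11.7% of combination summits, and at equal length the 1 kb shares were 19.3% for SHP1705, 2.58% for MG132 and 2.78% for the combination. List and direction combinations past the outer percentiles numbered 2 at 50 kb, neither of them among the 11 at 10 kb, with 80.2% to 97.2% of all genes near a region at that distance.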

Other observations

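These transcripts were singled out after their values were seen, and heights are given per 1000000 fragments. PLAT, which encodes tissue plasminogen activator, reached a pileup of 879.6 in SHP1705 and 11.2 in DMSO. COL6A2, a collagen VI chain, reached 760.3 and 16.2, SPARC, a matrix glycoprotein, 475 and 13.3, and the fibrillar collagen COL1A2 279 and 8.98. The chaperone genes HSPA5 and HSPA8 reached 282 and 202 in SHP1705, against 7.87 and 5.55 in DMSO, 9.23 and 5.31 in MG132, and 7.69 and 6.67 in the combination. At HSPA1A, an inducible heat shock gene, the highest pileup was 9.74 in SHP1705 and 0.707 in DMSO, and MG132 and the combination had no peak. The DMSO peak there held 21 fragments before scaling. Every transcript examined that had a DMSO peak stood higher in SHP1705, from 13.8 times at HSPA1A to 79.2 times at VIM. The higher values were thus shared across the transcripts examined. As these were picked after their values were seen, they do not show how other genes behave. A drug response of these genes was not tested.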
